A study of Malus domestica with 36 samples.

How the data were processed

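Peel RNA of 'Granny Smith' apples in 12 groups of 3 biological replicates was extracted with a plant RNA kit and made into non-directional libraries, per the labels, and read on an Illumina HiSeq. The submitters' processing notes name HISAT2, StringTie and DESeq2, with no versions, and no genome build is given. The deposited table holds 57423 genes in 36 columns, 1 per library. The columns of the DCA_CF samples are headed DCA, without CF, and were matched to the sample titles by time, SL tag and letter. Although its sheet is named for counts, the values deposited by the authors are FPKM (fragments per kilobase of gene, scaled to the reads of the library), read as such because they are not whole and because low values of a gene are multiples of a step that depends on gene and library. TPM with some genes left out cannot be told from FPKM here. As the values are not counts, count models were not used, and limma 3.58.1 in R 4.3.3 was run in their place, the fallback fixed before the data were examined.

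Gene names are the NCBI symbols and LOC identifiers of the table, with 34074 identifiers found in a RefSeq gene table of apple, used for names and synonyms and, in 1 test of neighbouring genes, for the order of genes. Of the genes tested, 571 (1.73%) carry a name, so groups of named genes cover a small part of the transcriptome. Since no build is stated, no coordinates are given. The libraries were non-directional, so antisense transcripts are counted with genes, and reads of close family members such as allergen or PGIP genes can be shared.

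Values were transformed as log2(FPKM + 1), which understates fold changes of low genes. Genes with at least 1 FPKM in at least 3 libraries were kept, 32923 in all. A linear model with 1 mean per group was fitted over all 36 libraries, with moderated variances that follow the mean (eBayes, trend), and 17 contrasts of group means were tested. Adjusted p is Benjamini-Hochberg over all genes, with an FDR threshold of 0.05. No further scaling between libraries was applied. Counts of genes changed at least 2-fold are on the log2(FPKM + 1) scale and were added after the data were seen.

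Of 31 gene lists fixed before the data were examined as patterns in gene descriptions, only the WRKY list reached 5 measured members, because most genes have no description. A further 25 lists of symbols were therefore made after the table was seen and before any test, and 24 had enough members. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists of a contrast. The rule for named genes, fixed beforehand, takes per contrast up to 6 genes with the largest change in each direction. These are named genes with an FDR under 0.05, a mean log2 level of at least 2 and no overlap between the compared groups. The lack of overlap was not asked for the differences of the SL or time response. It adds up to 2 members per list and direction by p. In each contrast it also takes the farnesene synthase, polyphenol oxidase, ACC synthase, ACC oxidase and alcohol dehydrogenase of highest level. Levels were compared only among named ACC synthases and ACC oxidases. AFS1, PPO and ADH1-1 were taken by symbol, so unnamed genes of these enzymes may lie higher. The mean log2(FPKM + 1) took the place of log2 CPM in the rule. No pyruvate decarboxylase or phenylalanine ammonia-lyase is named in the table.

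Alternatives were RLE and upper quartile scaling, no filter, the replicate letter as a block, fits of the compared libraries alone and leaving out each library in turn. A pseudocount of 0.1, scaling to a total of 1000000 and removal of genes listed at 0 beside a high replicate were added after the data were seen. Letters a, b and c do not pair libraries across groups: residuals correlated at a mean of 0.0051 for the same letter and -0.0026 for other letters, and 15 of 36 libraries were closest to one of their own letter. No 2 libraries of a group shared more than 0.382% of identical values among genes, so none was counted as a duplicate. The procedure was tested on simulated data with 200 genes changed. Its noise was normal, with 1 SD per gene for all groups. The shares below need not hold where groups differ in spread or where most genes change, as here. In DCA_CF against ULO at T1 without SL, 67.2% of genes moved by 0.5 on the log2 scale, 83.6% moved by 1 and 90.9% moved by 2 were recovered, with 7.47% false among those called. In the difference of the SL response between low oxygen and RA at T1, 46.3% of genes moved by 0.5, 82.1% moved by 1 and 87.9% moved by 2 were recovered, with 4.64% false among those called. Splits of the libraries into other groups were refitted in the same way.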

Results

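RNA from the peel of 'Granny Smith' apples was sequenced to follow gene expression during storage in several atmospheres, in a study of superficial scald, a browning disorder of the peel of stored apples. The 36 libraries fell into 12 groups of 3 biological replicates. The groups cross 3 storage regimes with 2 times, T1 and T2, and with the absence or presence of the tag SL. The regimes are RA, which the labels do not expand, ULO, at 1% oxygen, and DCA_CF, at under 1% oxygen. Neither the meaning of SL nor the length of storage at T1 and T2 is given. ULO and DCA_CF are called low oxygen here, and their mean was compared with RA.

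Summed values per library ran from 689868 to 790211 FPKM, and between 33512 and 37276 genes had a value above 0. Read totals were not used here, so the depth of each library is unknown and no counting interval can be given. Relative depths, read from the steps between low values of a gene, spanned 0.934 to 1.25. The median coefficient of variation between replicates was 3.77% to 6.52% per group for genes at 10 to 100 FPKM, and 13.9% to 17.3% at 1 to 3 FPKM. The first principal component held 34.1% of the variance and the second 22.5%. RA libraries without SL lay at the low end of the first component at both times, and the replicates of each group lay close together. How many fruits went into a library is not given, and tests against so small a spread call many genes with small changes. Below, a value after a gene is the log2 fold change ± the standard error of the fit, and a level is the mean ± SD in FPKM (n = 3 libraries). Genes described as higher, lower, risen or fallen passed an FDR of 0.05 in limma. Values for low oxygen average ULO and DCA_CF, and values over time also average the SL states. Fits of each regime and SL state apart were added after the results were seen, and are given where a part did not pass in the direction of the average or where parts differed by at least 1 on the log2 scale.

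**Figure D1:**
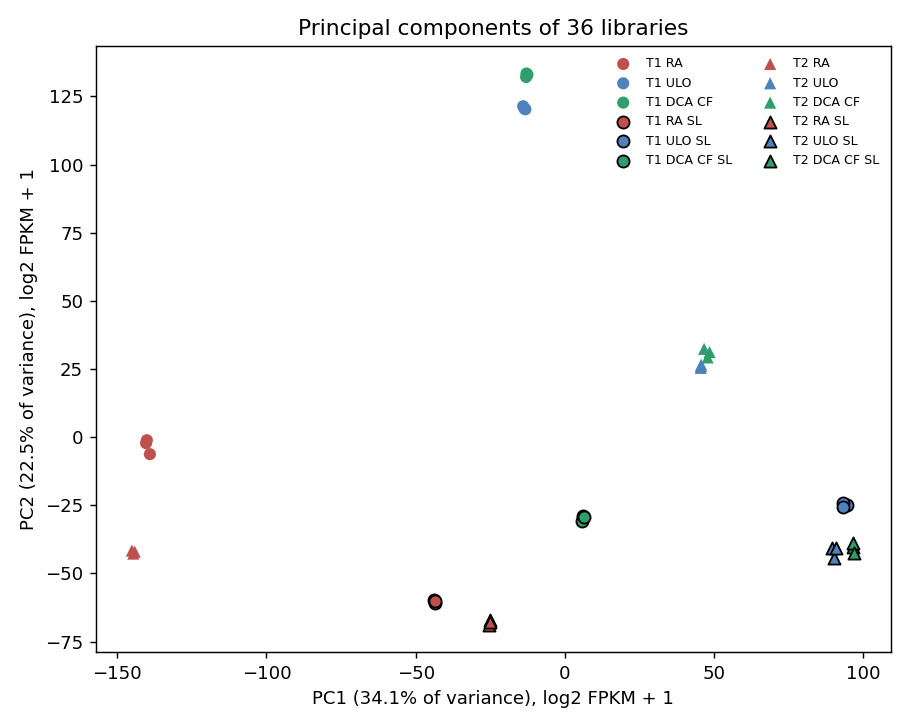
Principal components of log2(FPKM + 1) for the 36 libraries; each point is 1 library, colour gives the regime, shape the time, and a black edge the SL tag. The first axis holds 34.1% of the variance and the second 22.5%.

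To see how low oxygen altered the peel, its 2 regimes were compared with RA. At T1 without SL, PPO, a polyphenol oxidase whose products turn brown, fell by 5.89 on the log2 scale (-5.89 ± 0.0404), from 1308 ± 39.8 FPKM in RA to 18.2 ± 1.17 in ULO and 24.2 ± 1.102 in DCA_CF. PR1a (LOC103436302), a pathogenesis-related gene, changed by -7.46 ± 0.12, OSC4 (LOC103443364), an oxidosqualene cyclase of triterpene synthesis, by -6.42 ± 0.112, and CWI by -6.05 ± 0.0811. The heat shock factor LOC103424358 (synonym HSF1) changed by -5.78 ± 0.0722 and HSF6 (LOC103403040) by -5.62 ± 0.0773. On the other side, the NAC gene NAC10 (LOC103421355) was higher by 5.66 ± 0.132 and PIP1 by 5.37 ± 0.0496. DFR (LOC103450464), the dihydroflavonol reductase of anthocyanin synthesis, was listed at 0 in RA and at 12.4 ± 0.457 FPKM in ULO. IAA5 was higher by 3.51 ± 0.127 and HD7 (LOC103444266) by 3.06 ± 0.0452. Of the ethylene synthesis genes, ACS1 (LOC103405045) was higher by 0.97 ± 0.0561 and ACO1 (LOC103446762) by 0.45 ± 0.0371. AFS1 (LOC103446592), the synthase of the sesquiterpene alpha-farnesene, was lower at -0.44 ± 0.0238. ADH1-1 (LOC103428551), an alcohol dehydrogenase of fermentation, averaged 0.5 ± 0.0638, with a rise in DCA_CF alone (1.04 ± 0.0736) and -0.037 ± 0.0736 in ULO, short of the threshold.

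Of 8 heat shock factors and proteins, 1 was higher and 6 lower (camera adjusted p = 0.025). The heat shock gene HSP90.5 (LOC103402763) was higher by 0.34 ± 0.0285 and Hsp2 (LOC103435013) lower at -2.16 ± 0.0233 (ULO -1.36, DCA_CF -2.95). Of 15 homeodomain genes, 11 were higher and 3 lower (camera adjusted p = 0.025), among them HD12 (LOC103428301) at 2.32 ± 0.0324 and HD11 at -0.69 ± 0.0454. Of 17 MYBR genes, 13 were higher and 3 lower (camera adjusted p = 0.0251), among them MYBR7 at 2.04 ± 0.0682 and MYBR2 at -0.82 ± 0.0536. Of 38 AP2/ERF transcription factors, 22 were higher and 10 lower (camera adjusted p = 0.0302, and adjusted p = 0.158 with an estimated correlation), among them ERF1 (LOC103452857) at 1.77 ± 0.0255 and AP2D29 (LOC103453426) at -3.495 ± 0.0803 (ULO -2.98, DCA_CF -4.01). Of 9 Aux/IAA genes of auxin response, 6 were higher and 1 lower (camera adjusted p = 0.0491, and adjusted p = 0.158 with an estimated correlation, with no call for the list under upper quartile scaling or scaling to one total). Of 32 genes of the mitochondrial genome, 22 were higher and 4 lower (camera adjusted p = 0.0302, and adjusted p = 0.516 with an estimated correlation), among them matR at 1.37 ± 0.0983 and nad3 at -0.8 ± 0.182. The WRKY list, fixed before the data were examined, held 13 measured genes: 5 were higher and 7 lower, and adjusted over the list alone 5 and 7 (camera adjusted p = 0.208). In total 22449 of 32923 genes passed an FDR of 0.05, 11051 higher and 11398 lower, and 7010 of them also changed at least 2-fold, 3025 up and 3985 down. The balance of all genes turned with upper quartile scaling (11434 higher and 11038 lower) and with scaling to one total (11893 higher and 10605 lower). Of the genes called, 17501 passed in the same direction in ULO and in DCA_CF taken apart, and 183 passed in the opposite direction in 1 of them. These genes were tested with limma across all 36 libraries.

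With SL at T1, low oxygen again showed less PPO (-4.47 ± 0.0404, with -7.14 in ULO and -1.796 in DCA_CF). Its level was 936 ± 18.7 FPKM in RA, 269 ± 2.88 in DCA_CF and 5.67 ± 0.418 in ULO. The lipoxygenase LOX7a (LOC103433945) was lower at -4.47 ± 0.0759 (ULO -5.07, DCA_CF -3.87), CWI at -4.23 ± 0.0811 (ULO -6.23, DCA_CF -2.23) and the sorbitol transporter SOT5 (LOC103449824) at -4.07 ± 0.059 (ULO -5.08, DCA_CF -3.06). LOX5b (LOC103418601), another lipoxygenase, was higher by 3.77 ± 0.349, with uneven RA libraries at 50.6 ± 34.5 FPKM. IAA12 was higher by 3.31 ± 0.0764 and LOX6b (LOC103422578) by 3.25 ± 0.057. ADH1-1 was lower at -2.28 ± 0.0638 (ULO -3.39, DCA_CF -1.17), whereas ACS1 was higher by 0.502 ± 0.0561 and ACO1 by 0.33 ± 0.0371. AFS1 averaged -0.26 ± 0.0238: it was lower in DCA_CF (-0.49 ± 0.0275) and level with RA in ULO (-0.018 ± 0.0275). Aux/IAA genes were higher in 8 and lower in none of 9 cases (camera adjusted p = 3.06e-05). Of 6 cell wall enzymes, 5 were higher and 1 lower (camera adjusted p = 0.00121), among them PG1 at 2.23 ± 0.0402 and XET01 at -0.28 ± 0.0348. Of 12 bZIP factors, 7 were higher and 2 lower (camera adjusted p = 0.00948), among them BZIP16 at 1.04 ± 0.025 and BZIP19 (LOC103413649) at -0.39 ± 0.0583. Homeodomain genes were higher in 10 and lower in 1 of 15 cases (camera adjusted p = 0.00206), among them HD7 at 2.04 ± 0.0452 and HD21 (LOC103401624) at -0.66 ± 0.0474. Of 9 genes of isoprenoid and triterpene synthesis, none was higher and 6 lower (camera adjusted p = 0.000748), among them HMG1 (LOC103410649) at -1.52 ± 0.0269 and OSC3 (LOC103432258) at -1.06 ± 0.0412. HMG1 encodes the reductase that commits carbon to the mevalonate pathway. Of 5 dehydrins, 4 were higher and 1 lower (camera adjusted p = 0.0274, and adjusted p = 0.285 with an estimated correlation), among them DHN2 (LOC103401165) at 1.26 ± 0.0356. In ULO alone the dehydrins were 3 higher and 2 lower. Mitochondrial genome genes were higher in 1 and lower in 24 of 32 cases (camera adjusted p = 0.000748, and adjusted p = 0.414 with an estimated correlation), among them rps19 at 1.04 ± 0.205 and ccmC at -1.71 ± 0.127. Among the WRKY genes 3 were higher and 7 lower; adjusted over the list alone it was 3 and 8 (camera adjusted p = 0.0666). In this comparison 16732 of 32923 genes passed an FDR of 0.05, 9262 higher and 7470 lower, and 3230 of them also changed at least 2-fold, 1213 up and 2017 down. With RLE size factors the balance of all genes turned, to 7851 higher and 8491 lower. Taken apart, ULO and DCA_CF shared 11344 of the calls, and 308 genes passed against the average in 1 of them.

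At T2 without SL, CWI was lower in low oxygen at -7.34 ± 0.0811, PR1a at -7.26 ± 0.12, OSC4 at -6.55 ± 0.112 and PPO at -6.29 ± 0.0404 (ULO -5.77, DCA_CF -6.8). GDSL (LOC103421823) was higher by 4.81 ± 0.0504, PIP1 by 4.67 ± 0.0496, LOX6b by 3.995 ± 0.057, DFR by 3.67 ± 0.0984 and HD7 by 3.63 ± 0.0452. GAD1, a glutamate decarboxylase that makes gamma-aminobutyrate, was higher by 3.44 ± 0.0233, at 40.6 ± 1.71 FPKM in RA and 508 ± 3.61 in ULO. AFS1 was higher by 0.98 ± 0.0238 (ULO 1.75, DCA_CF 0.21), ACS1 by 1.74 ± 0.0561 and ACO1 by 0.91 ± 0.0371, whereas ADH1-1 was lower at -2.03 ± 0.0638. Isoprenoid and triterpene genes were higher in 1 and lower in 8 of 9 cases (camera adjusted p = 0.00164, and adjusted p = 0.0749 with an estimated correlation), among them HMG1 at -1.92 ± 0.0269. At T1 without SL the level of HMG1 was instead above RA in ULO and, more so, in DCA_CF, with the DCA_CF and RA values given further below. AP2/ERF factors were higher in 10 and lower in 25 of 38 cases (camera adjusted p = 0.00209, and adjusted p = 0.0898 with an estimated correlation), among them ERF1 at 2.15 ± 0.0255 and AP2D41 (LOC103415910) at -3.71 ± 0.0718. Of 13 TCP factors, 11 were higher and 1 lower (camera adjusted p = 0.0375, and adjusted p = 0.169 with an estimated correlation), among them TCP1 at 0.85 ± 0.035 and TCP12 (LOC103444756) at -1.49 ± 0.0777. For WRKY factors, 3 were higher and 7 lower, and 3 and 7 adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.0749 with an estimated correlation). The examples were WRKY3 at 1.58 ± 0.0628 and WRKY9 at -3.16 ± 0.0591. Here 23669 of 32923 genes passed an FDR of 0.05, 15242 higher and 8427 lower, and 8198 of them also changed at least 2-fold, 4107 up and 4091 down. The near balance past 2-fold was not kept with RLE size factors (2861 higher and 4615 lower) or upper quartile scaling (3391 higher and 4218 lower). Of the genes called, 20270 passed in the same direction in ULO and in DCA_CF taken apart, and 52 passed in the opposite direction in 1 of them. The median log2 fold change of all genes lay at 0.22 and at 0.042 with RLE size factors, which gave 11678 genes higher and 10719 lower.

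At T2 with SL, the flavonoid pathway set RA apart. CHS1 (LOC103421794), a chalcone synthase that opens the pathway, was lower in low oxygen at -8.204 ± 0.115, with 617 ± 13.9 FPKM in RA against 1.13 ± 0.471 in ULO and 1.09 ± 0.172 in DCA_CF. PPO was lower at -6.76 ± 0.0404, CHS-2 (LOC103443512) at -6.44 ± 0.0802, SOT5 at -5.29 ± 0.059, LOX7a at -5.16 ± 0.0759 and DFR at -5.05 ± 0.0984. Of 17 genes of the flavonoid and dihydrochalcone pathway, 1 was higher and 14 lower (camera adjusted p = 1.21e-10), among them MdF3H (LOC103436139) at -4.86 ± 0.0445 and F3H (LOC103400025) at -3.67 ± 0.0407. UGT88F1 (LOC103402192), the glucosyltransferase of phloridzin synthesis, was higher by 0.64 ± 0.0238. HD7 was higher by 3.53 ± 0.0452, LOX6b by 3.43 ± 0.057, GDSL by 3.29 ± 0.0504, RGL2a (LOC103444199) by 3.19 ± 0.0745 and DHN2 by 3.02 ± 0.0356. Among the Aux/IAA genes, 7 of 9 were higher and 0 lower (camera adjusted p = 3.88e-05), among them IAA12 at 2.58 ± 0.0764 and IAA4 at 1.64 ± 0.0528. Cell wall enzymes were higher in 5 and lower in 1 of 6 cases (camera adjusted p = 0.00254), among them PG1 at 1.69 ± 0.0402 and XET02 at -0.34 ± 0.0241, the latter in DCA_CF alone (-0.62 ± 0.0279). BZIP factors were higher in 8 and lower in 2 of 12 cases (camera adjusted p = 0.00253), among them BZIP16 at 1.098 ± 0.025. Among the homeodomain genes, 10 of 15 were higher and 3 lower (camera adjusted p = 0.029), among them HD21 at -1.71 ± 0.0474. Of 9 pathogenesis-related and allergen genes, 1 was higher and 6 lower (camera adjusted p = 0.00194, and adjusted p = 0.146 with an estimated correlation), among them MALD3 (LOC103450745) at 2.76 ± 0.0338 and PGIP1 (LOC103454277) at -1.9 ± 0.0255. MALD3 encodes a lipid transfer protein, an apple allergen, and its family members can share reads. Of 12 genes of ethylene perception and signalling, 6 were higher and 2 lower (camera adjusted p = 0.0141, and adjusted p = 0.324 with an estimated correlation). AFS1 was higher by 0.14 ± 0.0238, ACS1 by 0.69 ± 0.0561 and ACO1 by 0.37 ± 0.0371, and ADH1-1 was lower at -4.31 ± 0.0638. In the WRKY list 4 genes were higher and 8 lower, and 4 and 8 adjusted over the list alone (camera adjusted p = 0.0728). In all, 16242 of 32923 genes passed an FDR of 0.05, 6644 higher and 9598 lower, and 3968 of them also changed at least 2-fold, 999 up and 2969 down. Upper quartile scaling gave 9852 genes higher and 7753 lower. Taken apart, ULO and DCA_CF shared 13120 of the calls, and 3 genes passed against the average in 1 of them.

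**Figure D2:**
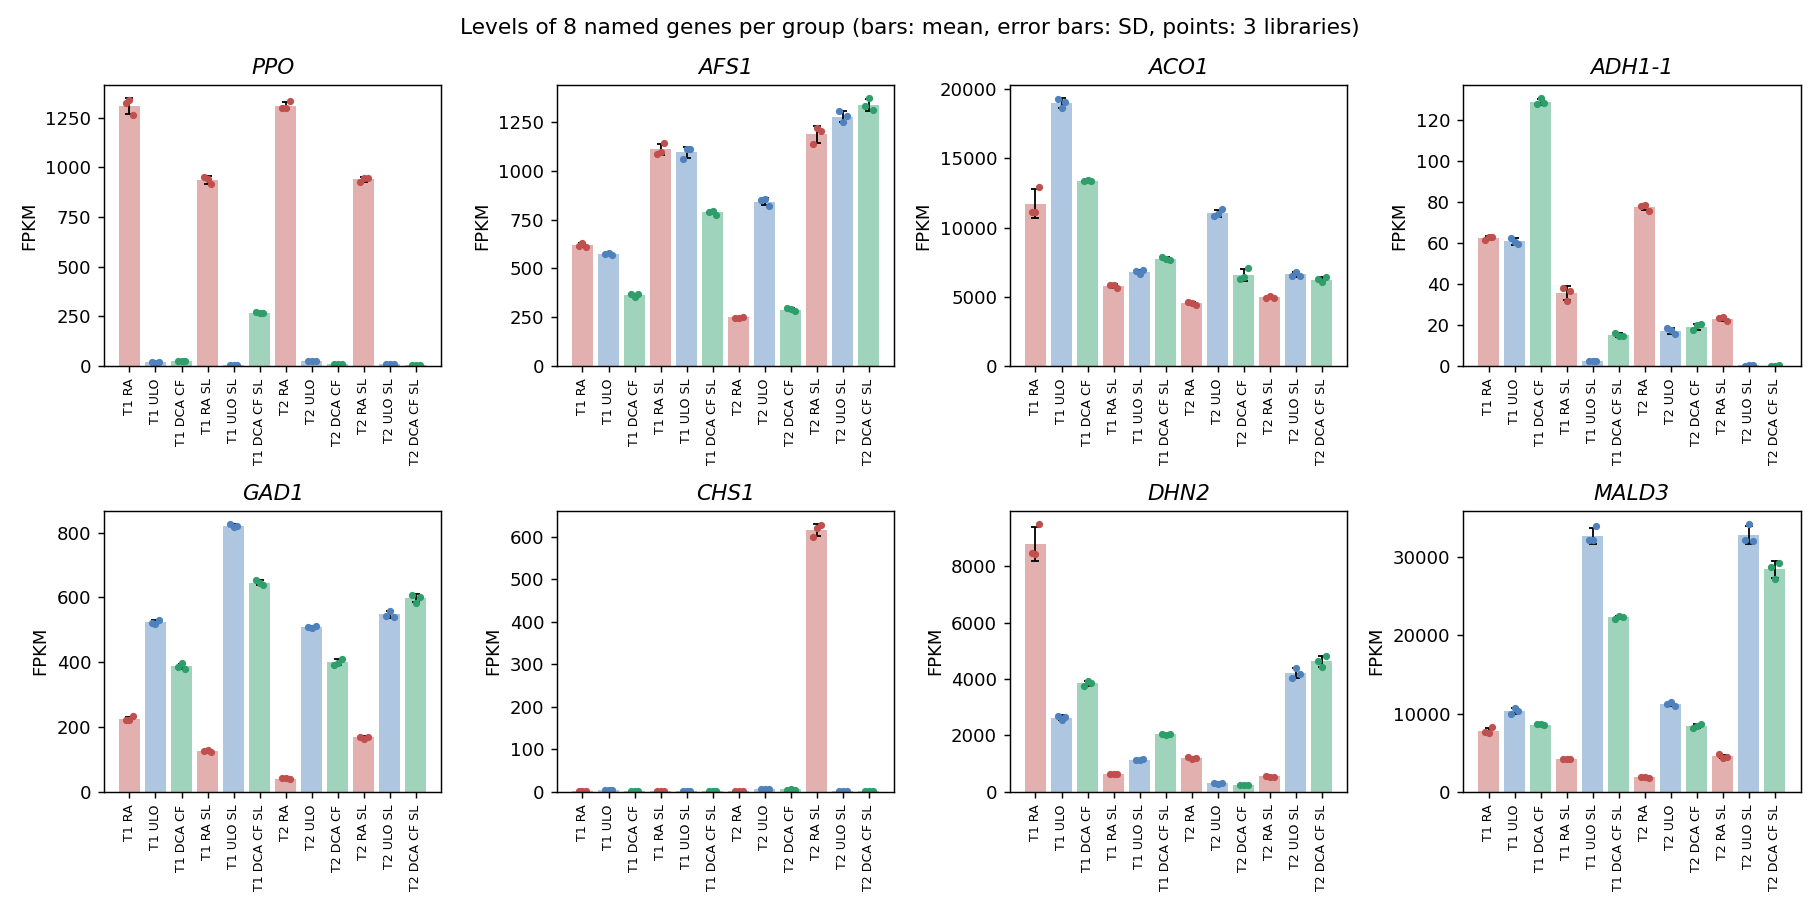
Levels of 8 named genes in FPKM (linear axis) for the 12 groups; bars are means, error bars SD, and points the 3 libraries of each group. The highest CHS1 bar is RA with SL at T2, at 617 FPKM, and PPO stands at 1308 FPKM in RA without SL at T1.

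To ask whether the 2 low oxygen regimes differed from each other, DCA_CF was compared with ULO. At T1 without SL, AP2D36 (LOC103414249) was higher in DCA_CF by 1.92 ± 0.0829, UGE by 1.69 ± 0.102 and AP2D4 (LOC103439588) by 1.57 ± 0.059. CAS2 (LOC103405317) was lower at -3.14 ± 0.0395 and AAT1 (LOC103406706), an acyltransferase of ester formation, at -2.21 ± 0.0305. ACO1 was lower at -0.504 ± 0.0428, ACS1 at -0.62 ± 0.0648 and AFS1 at -0.66 ± 0.0275, and ADH1-1 was higher by 1.07 ± 0.0736 and PPO by 0.39 ± 0.0466. Of 6 ethylene synthesis genes, none was higher and 5 lower (camera adjusted p = 0.0277, and adjusted p = 0.0753 with an estimated correlation). MYBR genes were higher in 9 and lower in none of 17 cases (camera adjusted p = 0.0128), among them MYBR13 at 0.84 ± 0.058. Among the AP2/ERF factors, 17 of 38 were higher and 7 lower (camera adjusted p = 0.0277, and adjusted p = 0.237 with an estimated correlation), among them AP2D47 (LOC103439589) at 1.4 ± 0.0492 and AP2D26 (LOC103452491) at -0.52 ± 0.0365. WRKY genes split into 5 higher and 2 lower, and adjusted over the list alone 6 and 2 (camera adjusted p = 0.226). In this test 13471 of 32923 genes passed an FDR of 0.05, 5452 higher and 8019 lower, and 973 of them also changed at least 2-fold, 480 up and 493 down. Past 2-fold the balance turned with RLE size factors (531 higher and 455 lower), with upper quartile scaling (498 higher and 484 lower), with scaling to one total (618 higher and 577 lower) and without ULO replicate a (517 higher and 499 lower).

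With SL at T1, PPO was higher in DCA_CF than in ULO by 5.34 ± 0.0466, CWI by 3.996 ± 0.0936, PR1a by 3.98 ± 0.139 and DHN5 (LOC103401182) by 3.55 ± 0.0787. OSC4 stood at 18.3 ± 2.73 FPKM in DCA_CF and near 0 in ULO. OMT1 (LOC103426312) was lower at -1.28 ± 0.0388, EXPA1 (LOC103447269), an expansin, at -0.85 ± 0.0889 and PG1, a polygalacturonase, at -0.83 ± 0.0465. AFS1 was lower at -0.48 ± 0.0275 and ACS1 at -0.55 ± 0.0648, and ADH1-1 was higher by 2.23 ± 0.0736. ACO1 was higher by 0.19 ± 0.0428, a call that ended at 0.072 with RLE size factors and at 0.035 with upper quartile scaling. Heat shock factors and proteins were higher in 5 and lower in none of 8 cases (camera adjusted p = 0.00641), among them LOC103424358 at 3.27 ± 0.0833 and HSF6 at 3.21 ± 0.0893. Of 9 Aux/IAA genes, none was higher and 6 lower (camera adjusted p = 0.00403), among them IAA4 at -0.42 ± 0.061. Flavonoid pathway genes were higher in 9 and lower in none of 17 cases (camera adjusted p = 0.0288, and adjusted p = 0.219 with an estimated correlation), among them UGT71K1 (LOC103447413) at 2.46 ± 0.0663. Among the isoprenoid and triterpene genes, 5 of 9 were higher and 1 lower (camera adjusted p = 0.0288, and adjusted p = 0.217 with an estimated correlation), among them HMG1 at 0.62 ± 0.031. Of 15 homeodomain genes, 1 was higher and 5 lower (camera adjusted p = 0.0288), among them HD3 at 0.28 ± 0.0555 and HD12 at -0.36 ± 0.0374. Among the bZIP factors, 1 of 12 was higher and 3 lower (camera adjusted p = 0.0288), among them BZIP5 at -0.46 ± 0.0325. Among the WRKY genes 7 were higher and 1 lower; adjusted over the list alone it was 7 and 3 (camera adjusted p = 0.15). Here 10303 of 32923 genes passed an FDR of 0.05, 7867 higher and 2436 lower, and 1741 of them also changed at least 2-fold, 1643 up and 98 down. RLE size factors gave 5824 genes higher and 4555 lower, and upper quartile scaling gave 5398 and 5762. A part of each DCA_CF sample in the state of RA is weighed further below and, together with other differences between the regimes, stays open. It would bear on all values of DCA_CF with SL at T1, also in the contrasts of SL and time and their differences.

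At T2 the regimes lay closer. Without SL, OMT1 was lower in DCA_CF at -2.77 ± 0.0388, PG1 at -2.702 ± 0.0465, UGT71A15 (LOC103441425) at -1.604 ± 0.04 and AFS1 at -1.54 ± 0.0275, from 842 ± 19.2 FPKM in ULO to 289 ± 8.03 in DCA_CF. ACO1 was lower at -0.74 ± 0.0428, ACS1 at -0.64 ± 0.0648 and PPO at -1.03 ± 0.0466, while ADH1-1 gave 0.16 ± 0.0736 with an adjusted p of 0.141. Pathogenesis-related and allergen genes were higher in none and lower in 6 of 9 cases (camera adjusted p = 8.39e-12), among them PGIP1 at -0.94 ± 0.0294 and PR-5a (LOC103411735) at -0.84 ± 0.029. Ethylene synthesis genes were higher in none and lower in 3 of 6 cases (camera adjusted p = 0.00967). Of 38 AP2/ERF factors, 16 were higher and 5 lower (camera adjusted p = 0.0205, and adjusted p = 0.146 with an estimated correlation), among them AP2D47 at 0.89 ± 0.0492 and AP2D11 at -0.32 ± 0.0255. Among the cell wall enzymes, 1 of 6 was higher and 4 lower (camera adjusted p = 0.0398, and adjusted p = 0.118 with an estimated correlation, with no call for the list under scaling of each library to one total), among them XET02 at 0.74 ± 0.0279. Of 18 NAC factors, 1 was higher and 6 lower (camera adjusted p = 0.0205, and adjusted p = 0.118 with an estimated correlation), among them NAC23 at -1.04 ± 0.109. For WRKY factors, 6 were higher and 0 lower, and 7 and 0 adjusted over the list alone (camera adjusted p = 0.0893). In this test 7557 of 32923 genes passed an FDR of 0.05, 4976 higher and 2581 lower, and 528 of them also changed at least 2-fold, 354 up and 174 down, and RLE size factors gave 3651 higher and 3441 lower. With SL at T2, MADS20 (LOC103416871) was higher by 0.71 ± 0.149 and IAA12 by 0.48 ± 0.0882, the latter with no call at a pseudocount of 0.1 (0.494), and HSF6 was lower at -0.64 ± 0.0893, GLB1 at -0.57 ± 0.0696, XET02 at -0.56 ± 0.0279 and PPO at -0.37 ± 0.0466. AFS1 at 0.067 ± 0.0275, ACS1 at -0.045 ± 0.0648, ACO1 at -0.083 ± 0.0428 and ADH1-1 at -0.14 ± 0.0736 did not pass. No list passed. In the WRKY list 0 genes were higher and 0 lower, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.826). There 1216 of 32923 genes passed an FDR of 0.05, 524 higher and 692 lower, and 40 of them also changed at least 2-fold, 14 up and 26 down. Past 2-fold the balance turned without ULO replicate a (31 higher and 26 lower) or c (35 higher and 31 lower). A fit of the compared libraries alone called 175 genes, 67 higher and 108 lower, and MADS20, HSF6, GLB1 and PPO did not pass in it.

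The groups tagged SL were then compared with the untagged groups of the same regime and time. In RA at T1, LOX5b rose by 4.69 ± 0.403, LOX5a (LOC103438366) by 4.52 ± 0.0512 and NAC10 by 3.75 ± 0.152. DHN5 changed by -4.82 ± 0.0787, DHN2 by -3.79 ± 0.0412 and PGIP1, an inhibitor of fungal polygalacturonases, by -3.5 ± 0.0294. AFS1 rose by 0.84 ± 0.0275 and ACS1 by 0.399 ± 0.0648, and ACO1 changed by -1.01 ± 0.0428, PPO by -0.48 ± 0.0466 and ADH1-1 by -0.801 ± 0.0736. Of 32 CIPK and SnRK2 kinases, 20 were higher and 6 lower (camera adjusted p = 0.00387), among them CIPK17 (LOC103439416) at 1.36 ± 0.0189 and SnRK2.8 (LOC103448631) at -1.42 ± 0.087. Of 13 lipoxygenases, 9 were higher and 3 lower (camera adjusted p = 0.0133, and adjusted p = 0.298 with an estimated correlation), among them LOX1a (LOC103411221) at 2.06 ± 0.0551 and LOX1c (LOC103433949) at -1.27 ± 0.0754. Homeodomain genes were higher in 10 and lower in 1 of 15 cases (camera adjusted p = 0.0239), among them HD16 at 2.2 ± 0.052 and HD6 at -0.39 ± 0.0616. WRKY genes split into 3 higher and 7 lower, and adjusted over the list alone 3 and 7 (camera adjusted p = 0.371). At T1 20297 of 32923 genes passed an FDR of 0.05, 8690 higher and 11607 lower, and 5646 of them also changed at least 2-fold, 2415 up and 3231 down. In RA at T2, CHS1 rose by 7.71 ± 0.132, DFR by 7.16 ± 0.114 from 0.331 ± 0.354 to 185 ± 6.803 FPKM, and LOX5b by 3.89 ± 0.403. EXPA1 changed by -4.596 ± 0.0889, OSC4 by -3.82 ± 0.13 and CWI by -3.67 ± 0.0936. AFS1 rose by 2.25 ± 0.0275 and ACS1 by 1.92 ± 0.0648. ACO1 rose by 0.13 ± 0.0428, a call that ended with RLE size factors (0.117) and without RA replicate c without SL (0.112). In the same groups ADH1-1 changed by -1.71 ± 0.0736 and PPO by -0.48 ± 0.0466. Among the flavonoid pathway genes, 13 of 17 were higher and 3 lower (camera adjusted p = 2.06e-07), among them F3H at 3.47 ± 0.047 and UGT71K1 at -0.71 ± 0.0663. Of 9 isoprenoid and triterpene genes, 1 was higher and 8 lower (camera adjusted p = 0.0204, and adjusted p = 0.154 with an estimated correlation), among them HMG1 at -0.92 ± 0.031. Among the homeodomain genes, 9 of 15 were higher and 3 lower (camera adjusted p = 0.0217), among them HD16 at 2.91 ± 0.052 and HD6 at -0.31 ± 0.0616. Among the WRKY genes 4 were higher and 6 lower; adjusted over the list alone it was 4 and 6 (camera adjusted p = 0.853). At T2 19365 of 32923 genes passed an FDR of 0.05, 8974 higher and 10391 lower, and 5399 of them also changed at least 2-fold, 2359 up and 3040 down.

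In low oxygen at T1, LOX5b rose with SL by 8.21 ± 0.285, OMT1 by 5.61 ± 0.0274 and LOX5a by 5.31 ± 0.0362 (ULO 4.68, DCA_CF 5.94). GLB1, a symbol used in Arabidopsis for a haemoglobin, changed by -4.91 ± 0.0492 (ULO -6.01, DCA_CF -3.81), PGIP1 by -4.37 ± 0.0208 (ULO -5.76, DCA_CF -2.98), AP2D24 (LOC103449153) by -4.28 ± 0.0501 and ADH1-1 by -3.58 ± 0.0521 (ULO -4.16, DCA_CF -3.003). AFS1 rose by 1.02 ± 0.0195 and ACO1 changed by -1.14 ± 0.0303. PPO went opposite ways in the regimes, with 3.42 ± 0.0466 in DCA_CF and -1.53 ± 0.0466 in ULO, so its average of 0.95 ± 0.033 describes neither. The DCA_CF value rests on SL libraries for which a part in the state of RA stays open. ACS1 gave -0.065 ± 0.0458 with an adjusted p of 0.205, and passed at -0.158 with each library scaled to one total. Among the mitochondrial genome genes, 2 of 32 were higher and 25 lower (camera adjusted p = 0.000119, and adjusted p = 0.472 with an estimated correlation), among them rps19 at 1.65 ± 0.168 and atp1 at -1.79 ± 0.0699. For WRKY factors, 4 were higher and 7 lower, and 4 and 7 adjusted over the list alone (camera adjusted p = 0.866). In this comparison 23855 of 32923 genes passed an FDR of 0.05, 11718 higher and 12137 lower, and 6821 of them also changed at least 2-fold, 3355 up and 3466 down. The balance of all genes turned with RLE size factors (12001 higher and 11842 lower) and upper quartile scaling (12411 higher and 11412 lower), as it did past 2-fold (3457 higher and 3386 lower, and 3614 higher and 3278 lower). Of the genes called, 15834 passed in the same direction in ULO and in DCA_CF taken apart, and 905 passed in the opposite direction in 1 of them. At T2, LOX5b rose by 4.93 ± 0.285, OMT1 by 4.65 ± 0.0274 (ULO 3.301, DCA_CF 5.999), DHN2 by 4.01 ± 0.0291, PF-1 (LOC103428897) by 3.85 ± 0.0583 (ULO 4.42, DCA_CF 3.29) and PG1 by 3.55 ± 0.0329 (ULO 2.29, DCA_CF 4.81). EXPA1 changed by -6.58 ± 0.0628 (ULO -7.11, DCA_CF -6.06), NAC10 by -4.37 ± 0.108, ADH1-1 by -3.98 ± 0.0521 and PPO by -0.95 ± 0.033. ACO1 averaged -0.41 ± 0.0303, from ULO (-0.74 ± 0.0428) and not DCA_CF (-0.077 ± 0.0428). AFS1 rose by 1.41 ± 0.0195 (ULO 0.601, DCA_CF 2.21) and ACS1 by 0.87 ± 0.0458. CIPK and SnRK2 kinases were higher in 17 and lower in 10 of 32 cases (camera adjusted p = 0.0345), among them CIPK17 at 1.22 ± 0.0133 and SnRK2.3 (LOC103402785) at -1.26 ± 0.0307. The kinases were 19 higher and 9 lower in ULO and near balance in DCA_CF, 14 higher and 13 lower. Of 15 homeodomain genes, 7 were higher and 4 lower (camera adjusted p = 0.0345), among them HD1 at 2.27 ± 0.0726 and HD6 at -0.58 ± 0.0435. In the WRKY list 6 genes were higher and 4 lower, and 6 and 4 adjusted over the list alone (camera adjusted p = 0.124). At T2 in low oxygen 22944 of 32923 genes passed an FDR of 0.05, 6546 higher and 16398 lower, and 5413 of them also changed at least 2-fold, 1321 up and 4092 down. The median log2 fold change of all genes lay at -0.23 and at -0.045 with RLE size factors, which gave 10053 genes higher and 12091 lower. Upper quartile scaling gave 10278 and 11944. The 100 highest genes held 17.15% to 18.72% of the summed FPKM per library in low oxygen without SL at T2, and 30.68% to 32.1% with SL. Whether this shift moved the median was not tested for this comparison. Taken apart, ULO and DCA_CF shared 16883 of the calls, and 98 genes passed against the average in 1 of them.

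T2 was then compared with T1, averaged over SL. In RA, MdF3H, a flavanone 3-hydroxylase, rose by 2.42 ± 0.0363 (0.33 without and 4.52 with SL) and XET02, a xyloglucan endotransglycosylase, by 1.26 ± 0.0197 (0.72 without and 1.79 with SL). S6PDH changed by -3.22 ± 0.611, with uneven libraries at 13.3 ± 12.4 FPKM in RA at T2, and GDSL by -1.73 ± 0.0412 (-2.69 without and -0.76 with SL). ACO1 changed by -0.798 ± 0.0303 (-1.37 without and -0.23 with SL). AFS1 and ACS1 averaged -0.605 ± 0.0195 and -0.48 ± 0.0458, but fell without SL (-1.31 ± 0.0275 and -1.24 ± 0.0648) and rose with SL (0.098 ± 0.0275 and 0.28 ± 0.0648). ADH1-1 rose without SL (0.31 ± 0.0736) and fell with SL (-0.599 ± 0.0736). Its average of -0.15 ± 0.0521 is a call that ended at a pseudocount of 0.1 (-0.154) and without RA SL replicate a (-0.122) or c (-0.133) at T1 or c (-0.129) at T2, and PPO gave 0.005 ± 0.033 with an adjusted p of 0.923. Of 17 flavonoid pathway genes, 12 were higher and 0 lower (camera adjusted p = 8.42e-11), among them CHS1 at 4.11 ± 0.0936. The counts were 5 higher and 3 lower without SL and 12 higher and 2 lower with SL, and CHS1 rose with SL (8.197 ± 0.132) but not without (0.03 ± 0.132). Among the pathogenesis-related and allergen genes, 2 of 9 were higher and 7 lower (camera adjusted p = 5.46e-08), among them PR-10a (LOC103425638) at 0.13 ± 0.0303 and PGIP1 at -1.17 ± 0.0208. In this list 0 higher and 6 lower was the count without SL and 5 higher and 3 lower with SL, where PGIP1 rose by 0.496 ± 0.0294 against -2.84 ± 0.0294 without SL, and PR-10a passed with SL alone. Of 32 mitochondrial genome genes, 1 was higher and 17 lower (camera adjusted p = 0.000661, and adjusted p = 0.486 with an estimated correlation), among them rps19 at 0.68 ± 0.168 and nad3 at -1.31 ± 0.149. Taken apart, rps19 passed without SL alone. WRKY genes split into 5 higher and 1 lower, and adjusted over the list alone 5 and 3 (camera adjusted p = 0.553). In RA 14754 of 32923 genes passed an FDR of 0.05, 8267 higher and 6487 lower, and 766 of them also changed at least 2-fold, 443 up and 323 down. Upper quartile scaling turned the balance of all genes, to 6955 higher and 7793 lower. Among all calls in RA, only 4052 passed in the same direction with and without SL, and 1531 passed in the opposite direction in 1 of the states. In low oxygen, Hsp2 rose by 1.99 ± 0.0134 (without SL 2.65 in ULO and 4.38 in DCA_CF, with SL 0.52 and 0.396) and HXK1 (LOC103400721), a hexokinase, by 1.16 ± 0.025 (without SL 1.61 in ULO and 2.04 in DCA_CF, with SL 0.504 and 0.48). LOX2a (LOC103449741) changed by -1.68 ± 0.037 (without SL -2.32 in ULO and -2.71 in DCA_CF, with SL -0.48 and -1.21), C3HL10 (LOC103417776) by -1.47 ± 0.0311 (without SL -2.37 in ULO and -2.07 in DCA_CF, with SL -0.69 and -0.76) and ADH1-1 by -2.43 ± 0.0368 (without SL -1.77 in ULO and -2.69 in DCA_CF, with SL -1.45 and -3.81). PPO averaged -1.34 ± 0.0233, carried by DCA_CF (-1.097 ± 0.0466 without and -5.14 ± 0.0466 with SL), while it rose in ULO (0.32 ± 0.0466 and 0.57 ± 0.0466). The DCA_CF value with SL starts from T1 libraries for which a part in the state of RA stays open. ACO1 averaged -0.54 ± 0.0214, with no call in ULO with SL (-0.043 ± 0.0428). AFS1 averaged 0.303 ± 0.0138 (without SL 0.55 in ULO and -0.33 in DCA_CF, with SL 0.22 and 0.77), and fell in DCA_CF without SL. ACS1 averaged 0 with an adjusted p of 0.995, since it fell without SL (-0.46 ± 0.0648 in ULO and -0.47 ± 0.0648 in DCA_CF) and rose with SL (0.22 ± 0.0648 and 0.72 ± 0.0648). AP2/ERF factors were higher in 6 and lower in 30 of 38 cases (camera adjusted p = 1.43e-06), among them AP2D29 at 1.51 ± 0.0464 (without SL 3.48 in ULO and 4.03 in DCA_CF, with SL -0.045 and -1.404) and AP2D50 (LOC103408131) at -2.47 ± 0.0456 (without SL -3.505 in ULO and -4.11 in DCA_CF, with SL -0.42 and -1.87). Taken apart, the list without SL was 7 higher and 28 lower in ULO and 6 higher and 26 lower in DCA_CF. With SL it was 13 higher and 14 lower in ULO and 10 higher and 16 lower in DCA_CF. The difference between the SL states was not itself tested. The rise of AP2D29 was limited to libraries without SL, and it fell in DCA_CF with SL. Of 9 pathogenesis-related and allergen genes, 2 were higher and 7 lower (camera adjusted p = 0.00135, and adjusted p = 0.219 with an estimated correlation), among them PGIP1 at -2.13 ± 0.0147 (without SL -2.495 in ULO and -3.32 in DCA_CF, with SL -0.019 and -2.69). In ULO with SL the list was 1 higher and 2 lower, and PGIP1 did not pass. Dehydrins were higher in none and lower in 5 of 5 cases (camera adjusted p = 0.0161, and adjusted p = 0.219 with an estimated correlation), among them DHN2 at -1.002 ± 0.0206. This average hides opposite changes: DHN2 fell without SL (-3.12 ± 0.0412 in ULO and -3.95 ± 0.0412 in DCA_CF) and rose with SL (1.89 ± 0.0412 and 1.18 ± 0.0412), and with SL the dehydrins were 3 higher and 1 lower in ULO and 3 higher and 2 lower in DCA_CF. Isoprenoid and triterpene genes were higher in 1 and lower in 5 of 9 cases (camera adjusted p = 0.0352, and adjusted p = 0.219 with an estimated correlation, with no call for the list under upper quartile scaling or scaling to one total), among them HMG1 at -1.55 ± 0.0155 (without SL -2.79 in ULO and -3.59 in DCA_CF, with SL 0.46 and -0.28). In ULO with SL this list was 3 higher and 1 lower, and HMG1 rose there. Mitochondrial genome genes were higher in 3 and lower in 23 of 32 cases (camera adjusted p = 0.00291, and adjusted p = 0.355 with an estimated correlation), among them atp1 at -0.91 ± 0.0494 (without SL -1.35 in ULO and -1.55 in DCA_CF, with SL 0.21 and -0.95). In ULO with SL these were 5 higher and 3 lower, with no call for atp1. Among the WRKY genes 1 was higher and 9 lower; adjusted over the list alone it was 1 and 9 (camera adjusted p = 0.0951). In low oxygen 23284 of 32923 genes passed an FDR of 0.05, 12358 higher and 10926 lower, and 2406 of them also changed at least 2-fold, 1194 up and 1212 down. The balance of all genes turned with RLE size factors (10815 higher and 12263 lower) and upper quartile scaling (11177 higher and 11977 lower). Among all calls in low oxygen, 2207 passed in the same direction in all 4 combinations of regime and SL state, and 5339 passed in the opposite direction in at least 1.

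**Figure D3:**
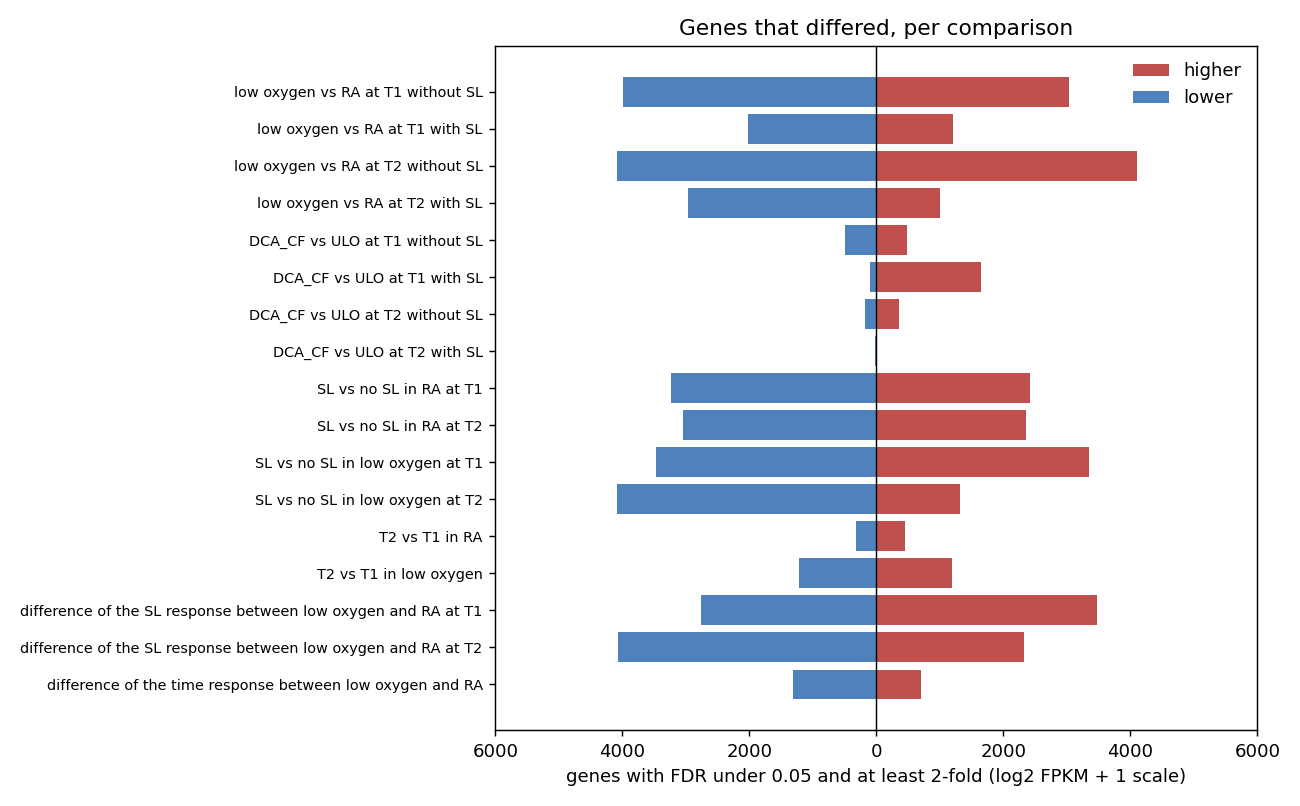
Genes with an FDR under 0.05 and a change of at least 2-fold in each of the 17 comparisons; bars to the right count genes that were higher and bars to the left genes that were lower. DCA_CF against ULO at T2 with SL has the shortest bars, 14 and 26 genes.

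Whether SL acted differently in low oxygen and in RA was tested as an interaction. At T1, the SL change of DHN5 exceeded that in RA by 5.94 ± 0.0964 (ULO 4.799, DCA_CF 7.08), that of PR1a by 3.98 ± 0.17 (ULO 1.97, DCA_CF 5.98) and that of OSC4 by 3.87 ± 0.159 (ULO 1.67, DCA_CF 6.08). Such an excess can reflect a fall in RA as well as a rise in low oxygen. For DHN5, the fall with SL in RA given above was about as large as the ULO excess. Its ULO value thus shows no rise in ULO, whereas in DCA_CF the excess was larger than that fall. Without SL, PR1a and OSC4 already lay at -7.46 and -6.42 against RA, and OSC4 stood near 0 in ULO with SL. NAC10 differed by -6.86 ± 0.187 and GLB1 by -4.64 ± 0.0852 (ULO -5.74, DCA_CF -3.54). ACS1 differed by -0.46 ± 0.0794 and ADH1-1 by -2.78 ± 0.0902 (ULO -3.36, DCA_CF -2.202). PPO averaged 1.43 ± 0.0571, with opposite signs in DCA_CF (3.903 ± 0.0659) and ULO (-1.05 ± 0.0659). For the DCA_CF libraries with SL a part in the state of RA stays open. AFS1 averaged 0.18 ± 0.0337 (no call at 0.09 with each library scaled to one total) and passed in DCA_CF alone (0.27 ± 0.0389, against 0.088 ± 0.0389 in ULO). ACO1 also had opposite signs, in ULO (-0.47 ± 0.0605) and DCA_CF (0.22 ± 0.0605). Its average of -0.12 ± 0.0524 was short of the threshold, which it passed with upper quartile scaling (-0.139), with scaling to one total (-0.212) and without RA replicate c (-0.192) or RA SL replicate c (-0.142), ULO replicate b (-0.128) or ULO SL replicate c (-0.126). Among the heat shock factors and proteins, 6 of 8 were higher and 0 lower (camera adjusted p = 0.00507) in this difference. Among the mitochondrial genome genes, 0 of 32 were higher and 26 lower (camera adjusted p = 3.16e-05, and adjusted p = 0.305 with an estimated correlation). Among the AP2/ERF factors, 10 of 38 were higher and 21 lower (camera adjusted p = 0.0206, and adjusted p = 0.232 with an estimated correlation). For WRKY factors, 5 were higher and 5 lower, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.555). In all 19278 of 32923 genes passed an FDR of 0.05, 10520 higher and 8758 lower, and 6233 of them also changed at least 2-fold, 3469 up and 2764 down. Scaling to one total turned the balance of all genes, to 9403 higher and 9695 lower. Of the genes called, 13082 passed in the same direction in ULO and in DCA_CF taken apart, and 343 passed in the opposite direction in 1 of them. At T2, CHS1 differed by -9.43 ± 0.162, DFR by -8.72 ± 0.139 and CHS-2 by -6.15 ± 0.113. The SL change of DHN2 exceeded that in RA by 5.16 ± 0.0504 and that of PR1a by 4.27 ± 0.17. PR1a lay at -7.26 against RA without SL, so its excess can also reflect a fall in RA. FIE (LOC103419005) passed as well, but it was listed at 0 in RA with SL and in DCA_CF without SL and was uneven elsewhere, as in ULO without SL at 8.07 ± 7.08 FPKM, so no size is given. ADH1-1 differed by -2.28 ± 0.0902, ACS1 by -1.05 ± 0.0794 and ACO1 by -0.54 ± 0.0524. AFS1 averaged -0.84 ± 0.0337 and PPO -0.47 ± 0.0571, both from ULO (-1.65 ± 0.0389 and -0.802 ± 0.0659), with no call in DCA_CF (-0.039 ± 0.0389 and -0.15 ± 0.0659). Flavonoid pathway genes were higher in 1 and lower in 13 of 17 cases (camera adjusted p = 5.23e-07). Of 38 AP2/ERF factors, 24 were higher and 6 lower (camera adjusted p = 3.01e-05). Among the isoprenoid and triterpene genes, 7 of 9 were higher and 1 lower (camera adjusted p = 0.000476). In the WRKY list 6 genes were higher and 3 lower, and 6 and 3 adjusted over the list alone (camera adjusted p = 0.163). At T2 19726 of 32923 genes passed an FDR of 0.05, 6292 higher and 13434 lower, and 6401 of them also changed at least 2-fold, 2324 up and 4077 down. The median log2 fold change of all genes lay at -0.23 and at -0.004217 with RLE size factors, which gave 9271 higher and 9107 lower, and upper quartile scaling gave 8591 and 9784. Past 2-fold RLE size factors turned the balance as well, to 2975 higher and 2742 lower. The unequal shares of the highest genes given for SL in low oxygen at T2 can bear on this median too, which was not tested. Taken apart, ULO and DCA_CF shared 15682 of the calls, and 32 genes passed against the average in 1 of them.

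The change from T1 to T2 also differed between low oxygen and RA. The values average 4 combinations of regime and SL state. The change of GDSL in low oxygen exceeded that in RA by 2.83 ± 0.0504 (without SL 4.52 in ULO and 5.44 in DCA_CF, with SL 0.39 and 0.97). That of ACBP2, a symbol of acyl-CoA-binding proteins, did so by 1.79 ± 0.061 (without SL 2.73 in ULO and 3.05 in DCA_CF, with SL 0.29 and 1.08). In RA GDSL fell (-2.69 without and -0.76 with SL), so its excess need not be a rise in low oxygen. Hsp2 averaged 1.803 ± 0.0233, from libraries without SL (2.75 ± 0.038 in ULO and 4.47 ± 0.038 in DCA_CF), with no call with SL (0.056 ± 0.038 and -0.07 ± 0.038). CHS1 averaged -3.62 ± 0.115: the difference was positive without SL (0.84 ± 0.187 in ULO and 1.34 ± 0.187 in DCA_CF) and negative with SL (-8.12 ± 0.187 and -8.53 ± 0.187). DFR passed as well, but it was listed at 0 in RA without SL at T1, so no size is given. GLB1 averaged -3.02 ± 0.0603 (without SL -5.27 in ULO and -5.12 in DCA_CF, with SL 0.36 and -2.05), with the opposite sign in ULO with SL. ADH1-1 differed by -2.28 ± 0.0638 (without SL -2.07 in ULO and -2.99 in DCA_CF, with SL -0.85 and -3.21) and AFS1 by 0.91 ± 0.0238 (without SL 1.86 in ULO and 0.98 in DCA_CF, with SL 0.12 and 0.67). PPO averaged -1.34 ± 0.0404, negative in DCA_CF (-1.1 ± 0.0659 without and -5.15 ± 0.0659 with SL) and positive in ULO (0.32 ± 0.0659 and 0.56 ± 0.0659). For the DCA_CF libraries with SL at T1 a part in the state of RA stays open. ACS1 averaged 0.48 ± 0.0561, with no call in ULO with SL (-0.059 ± 0.0916), and ACO1 0.26 ± 0.0371, with none in DCA_CF with SL (-0.087 ± 0.0605). Among the flavonoid pathway genes, 2 of 17 were higher and 11 lower (camera adjusted p = 7.65e-06). Without SL this list ran the other way, 8 higher and 2 lower in ULO and 7 higher and 2 lower in DCA_CF, against 2 higher and 12 lower and 0 higher and 15 lower with SL. AP2/ERF factors were higher in 9 and lower in 27 of 38 cases (camera adjusted p = 7.65e-06). In ULO with SL they were 12 higher and 10 lower. Of 9 isoprenoid and triterpene genes, 1 was higher and 6 lower (camera adjusted p = 0.0379, and adjusted p = 0.188 with an estimated correlation, with no call for the list under scaling of each library to one total). With SL the counts turned, to 6 higher and 0 lower in ULO and 4 higher and 3 lower in DCA_CF. NAC factors were higher in 4 and lower in 12 of 18 cases (camera adjusted p = 0.0311, and adjusted p = 0.126 with an estimated correlation). Without SL the NAC factors were near balance, 7 higher and 9 lower in ULO and 7 higher and 8 lower in DCA_CF, against 4 higher and 7 lower and 3 higher and 9 lower with SL. TCP factors were higher in 9 and lower in 1 of 13 cases (camera adjusted p = 0.0311, and adjusted p = 0.126 with an estimated correlation). With SL the TCP factors were 2 higher and 2 lower in ULO and 5 higher and 4 lower in DCA_CF. Of 15 genes of sorbitol, sucrose and starch metabolism, 10 were higher and 3 lower (camera adjusted p = 0.0311, and adjusted p = 0.188 with an estimated correlation, with no call for the list under scaling of each library to one total). In DCA_CF without SL they were 6 higher and 5 lower. WRKY genes split into 1 higher and 7 lower, and adjusted over the list alone 1 and 7 (camera adjusted p = 0.0311, and adjusted p = 0.0655 with an estimated correlation). Over both SL states 17936 of 32923 genes passed an FDR of 0.05, 9431 higher and 8505 lower, and 2020 of them also changed at least 2-fold, 703 up and 1317 down. The balance of all genes turned with RLE size factors (8489 higher and 9430 lower) and with scaling to one total (8656 higher and 9014 lower). Among all genes called, 1448 passed in the same direction in all 4 combinations, and 4159 passed in the opposite direction in at least 1.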

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

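The counts of other splits given here were set up after the results were seen. A test of the difference itself found that the SL response was unlike in low oxygen and RA at T1 for 19278 genes. Of 100 splits drawn with a fixed seed, 1, the real one, gave as many genes, and the highest other gave 15336. The median of the other splits was 1 gene, since splits that mix unlike groups raise the spread. The splits thus cannot exclude a chance difference between whole groups. Named genes past the threshold were DHN5 at 5.94, PR1a at 3.98, OSC4 at 3.87, NAC10 at -6.86, GLB1 at -4.64, ACS1 at -0.46 and ADH1-1 at -2.78 on the log2 scale. DHN5 fell with SL in RA, so its value is not a rise of that size in low oxygen. The regimes lay at least 1 apart for DHN5 (4.799 in ULO and 7.08 in DCA_CF), PR1a (1.97 and 5.98), OSC4 (1.67 and 6.08), GLB1 (-5.74 and -3.54) and ADH1-1 (-3.36 and -2.202). PPO averaged 1.43, with 3.903 in DCA_CF and -1.05 in ULO. The DCA_CF values rest on SL libraries for which a part in the state of RA stays open. AFS1 averaged 0.18 and passed in DCA_CF alone (0.27).

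At T2 the SL response differed between low oxygen and RA for 19726 genes. Of 100 splits drawn with a fixed seed, 1, the real one, gave as many genes, and the highest other gave 17408. The median of the other splits was 0, so the limit given for T1 holds here too. Genes that passed were CHS1 at -9.43, DFR at -8.72, CHS-2 at -6.15, DHN2 at 5.16, PR1a at 4.27, ADH1-1 at -2.28, ACS1 at -1.05 and ACO1 at -0.54. AFS1 averaged -0.84 and PPO -0.47, and taken apart both passed in ULO alone (-1.65 and -0.802). FIE passed too, but it was listed at 0 in 2 of the groups compared and in single libraries of others.

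The change from T1 to T2 differed between low oxygen and RA for 17936 genes. Of 100 splits drawn with a fixed seed, 1, the real one, gave as many genes, and the highest other gave 4049. With a median of 0 in the other splits, a chance difference between whole groups again cannot be excluded. Among all genes called, 1448 passed in the same direction in all 4 combinations of regime and SL state, and 4159 passed in the opposite direction in at least 1. Among named genes, the difference passed for GDSL at 2.83, ACBP2 at 1.79, ADH1-1 at -2.28 and AFS1 at 0.91. These passed in all parts but were uneven: GDSL was at 4.52 in ULO and 5.44 in DCA_CF without SL and at 0.39 and 0.97 with SL, ACBP2 at 2.73 and 3.05 against 0.29 and 1.08, ADH1-1 at -2.07 and -2.99 against -0.85 and -3.21, and AFS1 at 1.86 and 0.98 against 0.12 and 0.67. Averages that parts did not share were Hsp2 at 1.803, CHS1 at -3.62, GLB1 at -3.02, PPO at -1.34, ACS1 at 0.48 and ACO1 at 0.26: CHS1 had the opposite sign without SL (0.84 in ULO and 1.34 in DCA_CF), PPO in ULO (0.32 without and 0.56 with SL) and GLB1 in ULO with SL (0.36), and Hsp2, ACS1 and ACO1 did not pass in some parts.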

How the results depend on the processing

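The pseudocount of 0.1, scaling to one total, removal of genes listed at 0 beside a high replicate, upper quartile scaling of the lists and single-gene fits of the compared libraries were chosen after seeing the data; the other alternatives were planned. The count of genes past FDR 0.05 stayed within 1.5 times its value in all 17 comparisons under RLE and upper quartile scaling, no filter, the replicate block (22418 for low oxygen against RA at T1 without SL and 1180 for DCA_CF against ULO at T2 with SL) and each library left out, whose range for the latter was 875 to 1031. The exception was DCA_CF against ULO at T2 with SL in a fit of the compared libraries alone, at 175 against 1216. That fit has fewer libraries to estimate the spread. So have the other comparisons of 3 against 3 libraries, which stayed within 1.5 times, but their changes were larger. The median absolute log2 fold change of all genes was 0.0861 here and 0.1495 to 0.4291 there. They thus cannot tell whether fewer libraries account for the drop. The median variation at 10 to 100 FPKM was 5% in this DCA_CF group and 5.71% in this ULO group, where groups ranged from 3.77% to 6.52%. Whether the spread pooled over all groups understates theirs was not tested. Pairs of list and comparison past the threshold numbered 68 of 408, 35 with an estimated correlation, 348 with fry, which compares a list with no other genes, and 104 with no filter. With fry, 30 of these pairs turned direction against camera. RLE size factors turned none. ACS1 between the times in low oxygen went from 0 to -0.065 with RLE size factors and then passed; the cause was not tested. Of 270 gene values in the text, RLE size factors left 267 on their side of the threshold. Counts of genes past 2-fold depend on the pseudocount: with 0.1 they were 5394 and 6187 for low oxygen against RA with SL at T1 and T2, 2212, 3392, 1092 and 203 for DCA_CF against ULO in the order of the report, 10297 and 8752 for SL in low oxygen, 1899 and 5365 for time in RA and low oxygen, and 4366 for the difference in time. For DCA_CF against ULO at T2 with SL the count past 2-fold was 23 in the compared libraries alone, and 65, 62 and 66 without DCA_CF replicates a or c or ULO replicate c. The DESeq2 test was not run, since the values are not counts.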

Other observations

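The tests of scaling and depth for the first pattern below, of the scaling behind the shifted median, of a single share per gene, of the spread at 10 to 100 FPKM and of other splits were chosen after the results were seen. Genes in the next sentences were chosen after their values were seen. HMG1, of the mevalonate pathway, peaked at 3284 ± 16.1 FPKM in DCA_CF without SL at T1, against 841 ± 37.1 in RA, and ULO also lay above RA there. This was the reverse of its lower values in low oxygen at T1 with SL and at T2 without SL. MALD3 reached 32820.4 ± 1209.6 FPKM in ULO with SL at T2 and 1856 ± 68.4 in RA without SL. The mitochondrial rRNA 18rrn ran from 745 ± 101 FPKM in RA without SL to 44.7 ± 0.173 in ULO with SL at T1.

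With SL at T1, 1643 genes were at least 2-fold higher in DCA_CF than in ULO and 98 lower. Scaling does not account for this, since 90.2% were still higher with upper quartile scaling, nor does depth, with a ratio of 1.02 between ULO and DCA_CF. A candidate explanation is that part of each DCA_CF sample was in the state of RA. The median share of the way from ULO to RA was 0.259 for 570 genes far higher in RA and 0.281 for 166 far lower, a difference of -0.022 and the outcome such a mixture would give, in the test set beforehand, whereas in the test added later only 25.3% of the 736 genes lay within 3 standard errors of one share. A fixed mixture gives a single share for every gene, so a mixture alone is argued against for these genes. A mixture together with other differences between the regimes stays open. So does a difference between the regimes without a mixture, as the 2 were not tested apart.

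At T2 without SL, the median of all genes lay 0.224 above 0 in low oxygen against RA. It was 0.209 after scaling outside the 100 highest genes, and 0.296 among 11335 genes with a mean of at least 10 FPKM, which argues against a few genes taking the signal and against low genes as the source. A scaling that sets these libraries too high cannot be told apart from a broad change. RLE size factors gave 0.042, but they centre the median whatever its cause. Upper quartile scaling, which equalises the upper quartile and not the median, gave 0.144. A change of many genes in storage stays open as well.

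In 2854 cases, over 952 genes, a gene was listed at 0 in at least 1 replicate and at 10 FPKM or more in another of the same group. Zeros numbered 1320 in replicate a, 1244 in b and 1271 in c, together more than the cases. Some cases thus had more than 1 replicate at 0. The test set beforehand for low sampling was undecided, with 5.99% of cases at 100 FPKM or more. A later test argues against sampling at this level in general, as the median variation of genes at 10 to 100 FPKM was at most 6.52%. It cannot decide for the genes of these cases, 2.75% of those tested, to which such a median hardly responds. The test set beforehand for reads given to a neighbouring gene covered the 768 cases with a known position. A neighbour lay at 0 in the opposite replicates in 1.69% of them, and genes drawn at random in 1.04%. In these cases this argues against a swap with a neighbour that was otherwise silent. A neighbour with reads of its own would not be scored, so a transfer of reads to such a gene stays open. The other cases, which are most of them, stay open too, a limit set after this outcome was seen. Also open is the assignment of reads to models in the authors' software, and no biological explanation was tested.

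Other splits of the same libraries were refitted. For low oxygen against RA, 1 of 84 splits, the real one, gave as many genes in each comparison. At T1 it gave 22449 genes against 16587 in the highest other split without SL, and 16732 against 12186 with SL. At T2 it gave 23669 against 17279 without SL, and 16242 against 10039 with SL. Medians of the other splits were 26, 7, 3 and 4 in this order, since splits that mix unlike groups raise the spread. The test thus cannot exclude a chance difference between whole groups. For SL in low oxygen and for time, 1 of 100 drawn splits, the real one, gave as many, with the same limit. For SL it gave 23855 genes against 18548 in the highest other split at T1, and 22944 against 18337 at T2. For time it gave 14754 genes against 10875 in the highest other split in RA, and 23284 against 13646 in low oxygen. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real one alone (1) gave the count: 13471 genes against 16 in the highest other split, 10303 genes against 10 in the highest other split, 7557 genes against 14 in the highest other split and 1216 genes against 19 in the highest other split for DCA_CF against ULO in the order of the report, and 20297 genes against 10 in the highest other split and 19365 genes against 8 in the highest other split for SL in RA at T1 and T2.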
